A study of Mus musculus with 21 samples.

How the data were processed

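A pair of sets of Affymetrix mouse arrays were used, each with its own value table. In the NMuMG set, cells were grown with 200 µM 4sU with or without 5 ng/ml TGF-b1 for 2 h. RNA was extracted, and for the newly made samples 4sU-labelled RNA was enriched with a mercury-based reagent. Total and enriched RNA were amplified over a pair of rounds before hybridisation, per the labels' protocols. In the NM18 set, cells received 25 nM siRNA, then 5 ng/ml TGF-b1 after 8 h, and RNA taken 48 h after transfection was labelled by in vitro transcription from the 3' end. Arrays were placed in groups by their titles and characteristics, with 12 NMuMG arrays in 4 groups of 3 and 9 NM18 arrays in 3 groups of 3. For array 1 of control siRNA without TGF-b1, as for array 1 of FoxQ1 siRNA, a free-text note gives a protocol for both siRNAs that includes TGF-b1, whereas its title and treatment label name no TGF-b1. The title and label were followed, and values against untreated cells rest on them. The design has no FoxQ1 siRNA group without TGF-b1.

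The deposited values were log2 expression values summarised per probe set by the authors. The log2 scale was inferred from the range of the values, 2.34 to 14.8 in the NMuMG table and 4.57 to 14.6 in the NM18 table, since no label states it, and fold changes rest on that inference. The method of background correction, summarisation and normalization was not given in the sources used here, and affy 1.18.2 is named in the submitters' processing notes without a role. The array medians were 5.96, 5.72, 5.94 and 5.72 (log2, mean of 3 arrays) for control newly made, control total, TGF-b1 newly made and TGF-b1 total RNA and 7.37 to 7.39 in the NM18 groups. Whether and how the authors scaled arrays to each other is not given in the sources used here, and the values are not read as amounts of RNA per cell. The tables were normalized separately, so levels were tested only within a table. Across tables only the results of these tests were compared, by overlaps of calls with Fisher's exact test and by 1 correlation of log2 changes across genes. Scanner files and present or absent calls were not used here. For arrays the number of arrays per group limits the precision.

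Probe sets were named from the platform's annotation, and symbols were updated through Entrez identifiers for 34741 NMuMG and 20351 NM18 probe sets, of which 0 were renamed. Of 45101 NMuMG probe sets 34945 had 1 gene symbol, 932 several, 9160 none and 64 were controls. Of 22690 NM18 probe sets the numbers were 20380, 691, 1555 and 64. Only probe sets with 1 symbol were named. The probe set with the highest mean over all arrays of its table stood for its gene, which gave 18193 and 12393 genes. Control probe sets were left out of all tests and used only to read RNA quality and ribosomal RNA.

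Group effects were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 fit per table over all its groups, two-sided, and Benjamini-Hochberg adjustment over all genes of a comparison. A gene is called at an adjusted p under 0.05. A value after ± is the standard error where it follows a log2 change and the SD over 3 arrays where it follows a level. Comparisons were TGF-b1 against control in newly made RNA and in total RNA, the difference of these effects as an interaction, newly made against total RNA in control cells, TGF-b1 at 40 h against none under control siRNA, FoxQ1 siRNA against control siRNA with TGF-b1, and FoxQ1 siRNA with TGF-b1 against untreated control siRNA. The replicates are described as biological, but whether total and newly made RNA of 1 number came from 1 culture is not stated.

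The 16 gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation, under which only the calls of early TGF-b/SMAD targets in newly made and total RNA at 2 h held. The lists held 396 genes, of which 364 were measured in NMuMG and 356 in NM18 cells. Median, mean and camera direction of a list differed in sign only in lists that were not called. Members were also counted with adjustment over the list alone. The groups, comparisons, their tests, the lists, the rule for named genes and the alternatives were chosen before the data were examined, except the alternatives and the tests of explanations that are said to have been chosen after seeing the data or the result.

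Named genes were a fixed set (Foxq1, Cdh1, Cdh2, Vim, Fn1, Snai1, Zeb1, Zeb2, Smad7, Id1, Id2, Id3, Junb, Klf10 and 1 gene not analysed here). To these were added, per comparison, genes among the 10 largest rises and 10 largest falls that were called with groups that did not overlap (5 and 5 for the interaction), and per list 2 to 4 members with the smallest p. Unnamed transcripts could be passed over. The interaction genes outside this rule (Egln3, Aldh1a1, Tspan8, Il33 and 3110009F21Rik) were chosen after their values were seen, as were the values of Atf3, Ocln and Mki67 with TGF-b1 at 40 h, which the rule named only with FoxQ1 siRNA.

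The replicate numbers in the titles could pair arrays, so the correlation of deviations from the group means was checked for same-numbered arrays. The lowest of 3 correlations was 0.34 for TGF-b1 in newly made RNA, 0.12 in total RNA and 0.23 for TGF-b1 at 40 h. It was 0.45 for FoxQ1 siRNA and 0.16 for FoxQ1 siRNA with TGF-b1 against untreated cells, so numbers were taken to pair these arrays. In newly made RNA, TGF-b1 array 2 correlated at 0.339 with control array 2 and at 0.347 with a control array of another number. For newly made against total RNA the correlations were 0.31, 0.02 and 0.24 for numbers 1, 2 and 3, so pairing held only for numbers 1 and 3. The values reported come from the planned fit without pairing, and the replicate block was run as an alternative. Within groups arrays correlated at 0.984 or higher and 0 pairs were identical. The Gapdh control probe sets had a 3' minus 5' difference of 2.94 ± 0.39 in TGF-b1 newly made and 1.89 ± 0.03 in TGF-b1 total RNA (log2, SD over 3 arrays), and between -0.15 and -0.13 in the NM18 group means.

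Alternatives tried were the replicate number as a block, median centring, quantile normalization, genes above the median level only, only the arrays of the groups compared, an intensity trend with robust estimation, the mean of all probe sets of a gene, leaving out cross-hybridising probe sets (names ending in _s_at, _x_at, _a_at or _f_at), every probe set on its own, and leaving out each array in turn. For comparisons with shared arrays, 100 simulations of unchanged groups were run. Intervals over genes came from 10000 bootstrap draws. The self-test drew data with the real spread and changed 200 genes by 0.5, 1 or 2 on the log2 scale. Over 18193 genes, limma recovered 23.9%, 91.0% and 100% of these sizes for TGF-b1 in newly made RNA (5 false calls). It recovered 17.9%, 100% and 100% in total RNA (8), 4.48%, 55.2% and 100% for the interaction (4) and 29.9%, 94.0% and 100% for newly made against total RNA (13). Over 12393 genes it recovered 68.7%, 98.5% and 100% for TGF-b1 at 40 h (8), 76.1%, 100% and 100% for FoxQ1 siRNA (12), and 76.1%, 97.0% and 100% for FoxQ1 siRNA with TGF-b1 against untreated cells (8). Overlaps and permutation tests were run in R, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for summaries and plots.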

Results

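Gene expression was measured on Affymetrix mouse arrays in cultured epithelial cells given transforming growth factor beta 1 (TGF-b1), a secreted factor that drives epithelial cells towards a mesenchymal state. In the first set, NMuMG cells, a mouse mammary gland epithelial line, received 200 µM 4-thiouridine (4sU) for 2 h with or without 5 ng/ml TGF-b1. 4sU is a uridine analogue that marks RNA made during the labelling time. Total RNA and the enriched 4sU-labelled fraction, called newly made RNA from here on, were hybridised separately, which gave 4 groups of 3 arrays and 18193 genes. In the second set, NM18 cells were transfected with 25 nM of a scrambled control siRNA or of an siRNA against FoxQ1, a forkhead transcription factor, and 5 ng/ml TGF-b1 was added 8 h later for 40 h. Its 3 groups of 3 arrays were control siRNA without TGF-b1, control siRNA with TGF-b1 and FoxQ1 siRNA with TGF-b1, and 12393 genes were measured. Array 1 of control siRNA without TGF-b1 was grouped by its title and treatment label, although a free-text note on it also speaks of TGF-b1. All values were on a log2 scale, replicates were described by the submitters as biological replicates, and the number of arrays per group (n = 3) limited the precision.

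The first comparison asked which genes NMuMG cells transcribed more or less within 2 h of TGF-b1, read in newly made RNA. Lce1f, a late cornified envelope gene, rose by 2.95 ± 0.18 (SE) on the log2 scale, from 5.14 ± 0.30 (SD, n = 3) to 8.09 ± 0.35 (SD, n = 3; limma adjusted p = 6.25e-08). Nfatc2, a calcium-regulated transcription factor, rose by 2.89 ± 0.14 (adjusted p = 8.62e-09), and the oxidised LDL receptor gene Olr1 rose by 2.78 ± 0.17. The cytokine gene Il11, a known TGF-b target, rose by 2.53 ± 0.27. The chemokine genes Ccl20 and Cxcl5 fell the most, by 3.43 ± 0.15 (adjusted p = 2.81e-09) and 2.80 ± 0.16, and Ccl20 went from 10.96 ± 0.16 to 7.53 ± 0.16 (SD, n = 3 each). The cytochrome P450 gene Cyp3a13 fell by 2.50 ± 0.13, the prolyl hydroxylase gene Egln3 by 2.00 ± 0.12 and the insulin receptor substrate gene Irs1 by 1.97 ± 0.15. In all, 1116 genes were called at adjusted p under 0.05, 609 higher and 507 lower, of which 160 and 90 changed by at least 2-fold, while 2866 genes had an unadjusted p under 0.05. With only the arrays of the groups compared 680 genes were called (373 higher and 307 lower). The replicate block gave 835 higher and 767 lower, and median centring 717 and 411. A block within each kind of RNA, chosen after seeing the data, gave 2320 (1121 and 1199). The split into higher and lower depended on single arrays: 565 and 723 without control array 1, 436 and 322 without control array 2, and 405 and 420 or 448 and 321 without TGF-b1 array 2 or 3.

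Early TGF-b/SMAD targets rose as a group in newly made RNA: 16 of 29 measured members rose and 0 fell (23 and 0 adjusted over the list alone, 24 of either sign at an unadjusted p under 0.05 with limma). Their median was 0.75 and the camera adjusted p 1.05e-25 (adjusted p = 0.00159 with an estimated correlation). Members included the sphingosine kinase gene Sphk1 (1.61 ± 0.16), the transcriptional repressor Bhlhe40 (1.51 ± 0.17), the inhibitory SMAD gene Smad7 (0.99 ± 0.11) and Klf10 (0.63 ± 0.11). Id3, an inhibitor of bHLH transcription factors, fell by 1.37 ± 0.16 (adjusted p = 4.09e-05), and Id2 had -0.63 (adjusted p = 0.0194, up to 0.0989 without TGF-b1 array 3). Foxq1 itself went from 9.28 ± 0.43 to 10.24 ± 0.36 (SD, n = 3 each), a rise of 0.95 ± 0.25 (adjusted p = 0.0292). That call was lost under quantile normalization (0.0587), with only the arrays of the groups compared (0.0628), without control array 2 (0.0927) or 3 (0.13) and without TGF-b1 array 1 (0.113) or 2 (0.0626). Its other probe set rose by 0.85 (adjusted p = 0.0137).

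EMT transcription factors as a list were higher in newly made RNA, with 3 of 17 members rising (6 higher adjusted over the list alone). The median was 0.22 and the camera adjusted p = 0.00662 (adjusted p = 0.206 with an estimated correlation, 0.0523 without TGF-b1 array 2). Ets1 had 0.70 (adjusted p = 0.00562, 0.0534 when number 1 was left out of every group). Zeb1, a repressor of epithelial genes, had 0.60 ± 0.18 (adjusted p = 0.0674, 0.00439 with the replicate block, 0.0383 with median centring, 0.0281 with quantile normalization), and Snai1 0.50 ± 0.17 (adjusted p = 0.116). Zeb2 (0.15), Cdh2 (-0.35), Vim (-0.28), Fn1 (0.34) and Id1 (-0.44) were not called either. Junb had 0.82 ± 0.28 (adjusted p = 0.116, 0.00434 with the replicate block). With a block within each kind of RNA, chosen after seeing the data, Snai1 (limma adjusted p = 0.0262) and Cdh2 (0.0337) were called too. E-cadherin (Cdh1), the main adhesion protein of epithelial junctions, stood at -0.06 ± 0.14 (adjusted p = 0.922).

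Of 27 mesenchymal and actin cytoskeleton genes, 5 rose and 0 fell in newly made RNA (6 and 0 adjusted over the list alone, 10 of either sign at an unadjusted p under 0.05 with limma), among them integrin beta 3 (Itgb3, 1.41 ± 0.20) and zyxin (Zyx, 0.68 ± 0.12). The camera adjusted p was 0.00302 (adjusted p = 0.502 with an estimated correlation, 0.0510 without control array 1). Extracellular matrix genes moved both ways: 4 of 37 rose and 2 fell (6 and 2 adjusted over the list alone). The laminin gene Lamb3 rose by 1.95 ± 0.17 and the lysyl hydroxylase gene Plod2 by 1.03 ± 0.19, whereas the collagenase gene Mmp13 fell by 1.69 ± 0.24. The camera adjusted p of this list was 0.0349 (adjusted p = 0.827 with an estimated correlation). It rose to 0.064 with median centring, 0.0761 for genes above the median level, 0.262 without control array 1 and 0.137 and 0.212 without TGF-b1 arrays 2 and 3. Cholesterol synthesis genes were lower as a list, with 0 of 16 higher and 1 lower (the same adjusted over the list alone, 2 at an unadjusted p under 0.05 with limma). The median was -0.21 and the camera adjusted p 0.0323 (adjusted p = 0.827 with an estimated correlation). This call was lost for genes above the median level (0.162), when number 1 was left out of every group (0.0814), without control arrays 2 (0.0524) and 3 (0.0524) and without TGF-b1 arrays 1 (0.159) and 3 (0.0509).

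Epithelial junction and polarity genes were not called as a list in newly made RNA (camera adjusted p = 0.501): 3 of 43 rose and 4 fell (8 and 4 adjusted over the list alone). Plakoglobin (Jup) rose by 0.85 ± 0.11, and the simple-epithelium keratin gene Krt19 fell by 1.09 ± 0.17, cingulin (Cgn) fell by 0.70 ± 0.13 and the polarity gene Pard6b fell by 0.63 ± 0.13. Immediate-early genes also split, 3 of 28 higher and 3 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.501). Egr2 rose by 2.50 ± 0.36 and Jun by 0.76 ± 0.12, while the mRNA-decay factor gene Zfp36 fell by 0.92 ± 0.12 and the phosphatase gene Dusp1 by 0.73 ± 0.16. In the glycolysis list (camera adjusted p = 0.767) 1 of 13 rose, hexokinase 2 (Hk2, 1.17 ± 0.15), and in the interferon list (0.719) 1 of 27 rose, Oasl2 (0.81 ± 0.13). The lists for cell cycle (1 of 29 lower, 0.458) and macrophage and leukocyte markers (1 of 13 lower, 0.791) were not called. Of the p53, oxidative phosphorylation, ribosomal protein, basal and fibroblast lists no member was called by limma (4, 1, 0, 2 and 1 members at an unadjusted p under 0.05), with camera adjusted p of 0.275, 0.274, 0.590, 0.606 and 0.791. Without control array 1 the oxidative phosphorylation list reached 0.0361. With the replicate block limma called Pdgfrb of the fibroblast list, as given under other observations.

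The same question was asked in total RNA of the NMuMG cells. Lce1f rose by 3.49 ± 0.18 (SE; limma adjusted p = 1.85e-08), Nfatc2 by 2.85 ± 0.14, Spsb1, an adaptor of ubiquitin ligases, by 2.83 ± 0.14 and Il11 by 2.41 ± 0.27. The kinase gene Pim1 rose by 1.93 ± 0.14. Cxcl5 fell by 2.90 ± 0.16 (adjusted p = 3.31e-08), Irs1 by 2.37 ± 0.15, Ccl20 by 1.88 ± 0.15, the chemokine gene Cxcl1 by 1.74 ± 0.11 and the forkhead factor gene Foxa2 by 1.69 ± 0.16. Total RNA gave 452 called genes, 266 higher and 186 lower (85 and 38 by at least 2-fold, 1752 at an unadjusted p under 0.05). With the replicate block 701 genes were called (402 higher and 299 lower). A block within each kind of RNA, chosen after seeing the data, gave 1025 (547 and 478). With only the arrays of the groups compared 586 were called (339 and 247), against 680 in newly made RNA under that setting. Without control array 1 there were 194 higher and 123 lower, and without TGF-b1 array 3 228 and 109. Of the genes called in total RNA, 246 were higher and 146 lower in newly made RNA as well, against 8.90 and 5.18 for independent lists, and 0 had opposite limma calls (6.23 and 7.41 for independent lists). Log2 changes in both kinds of RNA correlated across genes at Pearson r = 0.75, genes not being independent replicates. Independent lists are no measure of chance here, since labelled RNA is part of total RNA and both effects come from 1 fit. A shared culture is also not excluded.

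In total RNA, Foxq1 went from 8.79 ± 0.49 to 9.89 ± 0.24 (SD, n = 3 each), a rise of 1.10 ± 0.25 (SE; limma adjusted p = 0.0211). This call was lost under quantile normalization (0.0536) and without control array 2 (0.0951) or 3 (0.144) or TGF-b1 array 1 (0.132) or 2 (0.075). Of the early TGF-b/SMAD targets 15 of 29 rose and 0 fell (20 and 0 adjusted over the list alone, 21 of either sign at an unadjusted p under 0.05; median 0.73, camera adjusted p = 7e-36, adjusted p = 0.000471 with an estimated correlation). Among them were Bhlhe40 (1.68 ± 0.17), Smad7 (1.25 ± 0.11), the SMAD corepressor gene Skil (1.13 ± 0.12) and Klf10 (0.75 ± 0.11). Id3 fell by 1.49 ± 0.16, and Id2 had -0.71 (adjusted p = 0.015, 0.061 with quantile normalization). EMT transcription factors were higher as a list, 4 of 17 called and 0 lower (5 and 0 adjusted over the list alone, 6 of either sign at an unadjusted p under 0.05). Their camera adjusted p was 0.00689 (adjusted p = 0.180 with an estimated correlation). Ets1 rose by 0.82 ± 0.14, and Snai1 had 0.73 ± 0.17 (adjusted p = 0.0294, up to 0.181 when 1 array was left out). Among epithelial genes 3 of 43 rose and 2 fell (camera adjusted p = 0.258), with claudin 4 (Cldn4, 1.62 ± 0.21), Jup (0.80 ± 0.11) and the epithelial ETS factor gene Elf3 (0.64 ± 0.11) higher. Cdh1 (-0.07), Vim (-0.13), Fn1 (-0.03), Zeb1 (0.45) and Id1 (-0.77) were not called, and Junb had 0.78 (adjusted p = 0.272, 0.0137 with the replicate block). With a block within each kind of RNA, chosen after seeing the data, limma also called Zeb1 (adjusted p = 0.00783) and Id1 (0.00582).

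In total RNA the extracellular matrix list (1 of 37 higher, the same adjusted over the list alone, median 0.07) had a camera adjusted p of 0.012 (adjusted p = 0.548 with an estimated correlation). The call was lost without single arrays (0.193 without control array 1, 0.0836 and 0.121 without TGF-b1 arrays 2 and 3). The p53 list was lower, 2 of 18 called (3 adjusted over the list alone; median -0.16). Its camera adjusted p was 0.0193 (adjusted p = 0.480 with an estimated correlation, 0.211 for genes above the median level, 0.115 and 0.0635 without control array 3 and TGF-b1 array 3). Cholesterol synthesis had 0 of 16 members called by limma (1 lower adjusted over the list alone, 5 at an unadjusted p under 0.05). The median was -0.20 and the camera adjusted p 0.0111 (adjusted p = 0.480 with an estimated correlation, 0.105 for genes above the median level, 0.0926 and 0.0605 without control arrays 1 and 3, 0.0626 without TGF-b1 array 2). Immediate-early genes split again, 2 of 28 higher and 4 lower (camera adjusted p = 0.929), with Jun at 0.76 ± 0.12, Zfp36 at -1.16 ± 0.12 and Dusp1 at -0.99 ± 0.16. Hk2 (1.06 ± 0.15) and Oasl2 (0.72 ± 0.13) rose within lists that were not called (glycolysis 0.333, interferon 0.833). Camera adjusted p was 0.111 for mesenchymal genes (0.0303 without TGF-b1 array 1), 0.135 for cell cycle, 0.453 for oxidative phosphorylation, 0.258 for ribosomal proteins, 0.185 for basal markers and 0.780 for macrophage markers. Fibroblast markers had 0.139 (0.0251 with the replicate block, 0.0337 without TGF-b1 array 1), and without control array 2 the cell cycle (0.0153), oxidative phosphorylation (0.0441), ribosomal protein (0.00717) and fibroblast lists (0.0249) were called.

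Whether TGF-b1 changed newly made RNA more or less than total RNA was tested as an interaction, which called 12 genes (532 at an unadjusted p under 0.05). The vanin gene Vnn1, which encodes a pantetheinase, fell by 1.96 ± 0.12 (SE) in newly made RNA and had -0.21 in total RNA, a difference of -1.75 ± 0.17 (limma adjusted p = 0.000274). Cyp3a13 had -2.50 and -0.62, a difference of -1.88 ± 0.19 (adjusted p = 0.000274), and Ccl20 -3.43 and -1.88, a difference of -1.55 ± 0.21 (adjusted p = 0.00757). Egln3 differed by -1.26 ± 0.17 (adjusted p = 0.00757). Lower in the same way were the aldo-keto reductase genes Akr1c14 (-1.73 ± 0.27) and Akr1c19 (-1.73 ± 0.26; adjusted p = 0.0171 for both). The retinaldehyde dehydrogenase gene Aldh1a1 (-1.21 ± 0.18), the tetraspanin gene Tspan8 (-1.14 ± 0.18) and the alarmin gene Il33 (-1.002 ± 0.149) had the same adjusted p. Ctla2a (1.34 ± 0.21) and Epb41l4b (1.01 ± 0.15) rose more in newly made RNA (adjusted p = 0.0171 for both). The remaining gene, the RIKEN clone 3110009F21Rik, had -1.55 (adjusted p = 0.0235, up to 0.108 without total TGF-b1 array 1). Foxq1 had a difference of -0.15 ± 0.35 and was not called.

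The number of interaction genes depended on single arrays. It was 20 without array 1 of newly made control RNA, 6 and 5 without arrays 2 and 3 of that group, 5 without total control array 1 or 2, 7 without newly made TGF-b1 array 3 and 4 without total TGF-b1 array 1 or 2. The number was 39 with the replicate block and 19 with quantile normalization. It was 86 with a block within each kind of RNA and 25 without number 1 in every group, both chosen after seeing the data. Vnn1, Cyp3a13 and Ccl20 passed the threshold under each alternative run, and Egln3 under each but the mean of all probe sets (-0.78, limma adjusted p = 0.0988). The other calls were each lost without at least 5 single arrays. The adjusted p reached 0.0912 for Akr1c14 without total control array 2 and 0.0753 for Akr1c19 without total TGF-b1 array 2. It reached 0.0798 for Aldh1a1, 0.0924 for Tspan8, 0.0798 for Il33 and 0.0798 for Ctla2a without total TGF-b1 array 1. Without number 1 in every group Il33 had 0.223 and Ctla2a 0.101. Epb41l4b had 0.31 (adjusted p = 1) with the mean of all probe sets and 0.0718 without array 2 of newly made control RNA. Of the 16 lists camera called none. The mesenchymal list was closest (median 0.15, 0 of 27 members called by limma, 2 at an unadjusted p under 0.05, camera adjusted p = 0.071). It was called without newly made control array 2 (0.0157) or 3 (0.0361), newly made TGF-b1 array 1 (0.00331) or total TGF-b1 array 3 (0.0154). Without total control array 3 the oxidative phosphorylation list was called (0.0246).

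**Figure D1:**
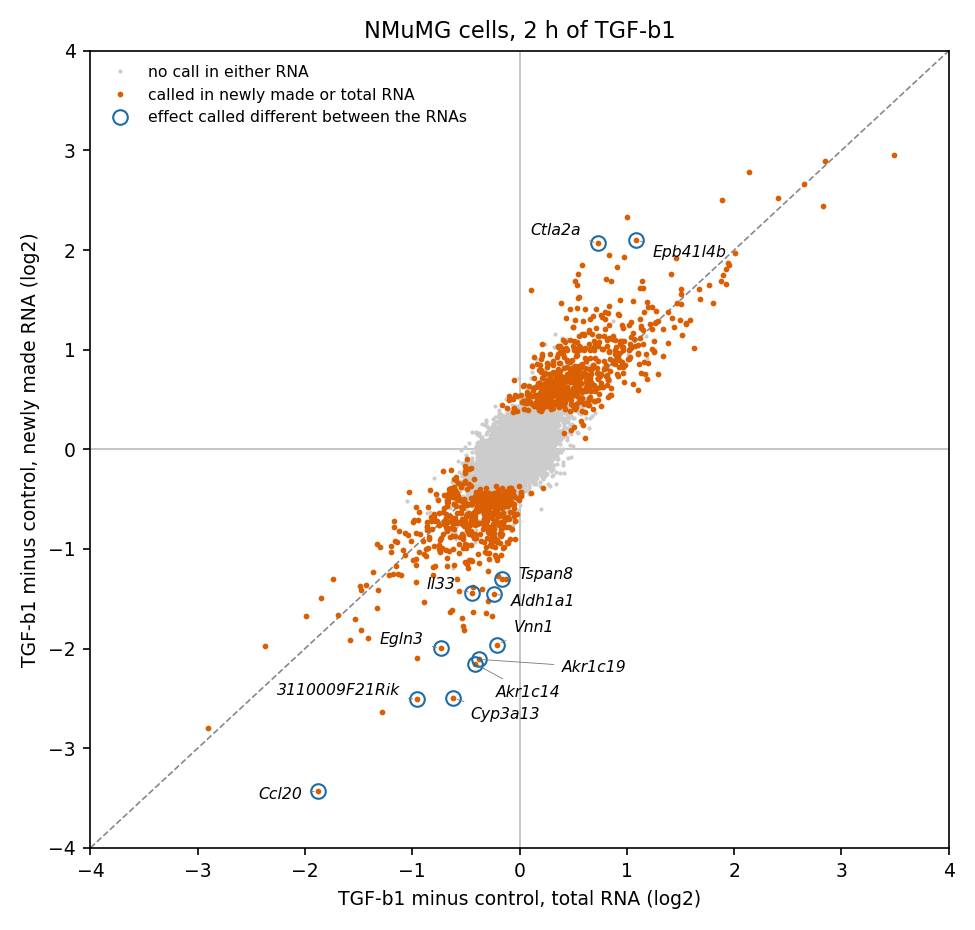
Each point is a gene, with its TGF-b1 effect after 2 h (log2 fold change, 3 arrays per group) in total RNA on the x axis and in newly made RNA on the y axis. Orange marks genes called in either kind of RNA, grey the others, blue circles the 12 genes whose effects differed, and the dashed line equal effects. The circled Vnn1 lies at -0.21 and -1.96 and Cyp3a13 at -0.62 and -2.50, below the dashed line, while Lce1f lies at 3.49 and 2.95.

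In control NMuMG cells, newly made RNA was compared with total RNA to see which transcripts made up more or less of the RNA of the last 2 h. The cell cycle inhibitor gene Cdkn1b was 3.65 ± 0.35 (SE, log2) higher in newly made RNA (limma adjusted p = 2.35e-07). The splicing factor gene Rbm4b was 3.25 ± 0.14 higher, the DNA demethylase gene Tet2 2.91 ± 0.13 and the cyclin gene Ccnt2 2.88 ± 0.14. The surface glycoprotein gene Cd99 was lower by -2.96 ± 0.14 (adjusted p = 7.06e-10), Lamb3 by -2.91 ± 0.17, Krt19 by -2.79 ± 0.17 and basigin (Bsg) by -2.74 ± 0.13. Of 18193 genes 8008 were called, 3131 higher and 4877 lower in newly made RNA (1327 and 1990 by at least 2-fold; 8996 at an unadjusted p under 0.05). The median over all genes was -0.08 here, 0.03 with median centring and -0.18 with quantile normalization, and the changes are read relative to it. Median centring gave 3828 higher and 4035 lower genes and quantile normalization 3150 and 6663. The size of the excess of lower genes therefore depends on the scaling. The Gapdh control probe sets gave a 3' minus 5' difference of 3.10 ± 0.55 in newly made and 1.81 ± 0.16 in total control RNA (log2, SD, n = 3). The 18S rRNA control probe set stood at 11.5 ± 0.27 and 13.4 ± 0.33.

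All 23 measured oxidative phosphorylation genes were called lower in newly made RNA (23 adjusted over the list alone; median -1.70, camera adjusted p = 2.93e-11, adjusted p = 0.147 with an estimated correlation), for example Atp5o (-2.37 ± 0.15) and Ndufa4 (-2.24 ± 0.15). All 22 ribosomal protein genes were lower too (22 adjusted over the list alone; median -1.53, camera adjusted p = 2.93e-11, adjusted p = 0.147 with an estimated correlation, 0.0637 without cross-hybridising probe sets). Rpl14 had -2.24 ± 0.12 and Rpl19 -1.93 ± 0.16. The counts of 23 and 22 depend on the probe set that stood for each gene. Without cross-hybridising probe sets, Cox5b of the oxidative phosphorylation list had 0.32 (limma adjusted p = 0.0294), an opposite call. The ribosomal protein gene Rpl35 had 0.32 under that setting and was not called (limma adjusted p = 0.119). In glycolysis 11 of 13 were lower and 1 higher (the same adjusted over the list alone; camera adjusted p = 0.000165, adjusted p = 0.120 with an estimated correlation, 0.233 without cross-hybridising probe sets). Aldoa stood at -2.19 ± 0.12 and Tpi1 at -1.65 ± 0.12. Epithelial genes were lower, 15 of 43 against 2 higher (the same adjusted over the list alone; camera adjusted p = 0.0183, adjusted p = 0.147 with an estimated correlation). The tight junction gene Lsr stood at -2.05 ± 0.20 and Cdh1 at -1.08 ± 0.14. Mesenchymal genes were lower, 14 of 27 against 2 higher (the same adjusted over the list alone; camera adjusted p = 0.0183, adjusted p = 0.403 with an estimated correlation). They were not called under quantile normalization (0.352), above the median level (0.152), with the mean of all probe sets (0.124) or without cross-hybridising probe sets (0.0512). Vim had -1.57 here and -0.07 (adjusted p = 0.766) under quantile normalization. Fn1 had -1.28, 0.56 with the mean of its probe sets, and its other probe set had an opposite call, as did 1 of 2 probe sets of Cdh2 (0.57, adjusted p = 0.00504).

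EMT transcription factors had 8 of 17 higher and 1 lower in newly made RNA (9 and 1 adjusted over the list alone; median 0.67, camera adjusted p = 0.000844, adjusted p = 0.120 with an estimated correlation). Zeb2 stood at 1.77 ± 0.13 and Zeb1 at 1.24 ± 0.18. Early TGF-b/SMAD targets had 12 of 29 higher and 1 lower (the same adjusted over the list alone; camera adjusted p = 0.000206, adjusted p = 0.147 with an estimated correlation). The hyaluronan synthase gene Has2 stood at 2.64 ± 0.28, Skil at 1.77 ± 0.12 and Smad7 at 1.00 ± 0.11. The p53 targets had 10 of 18 higher and 2 lower (the same adjusted over the list alone; camera adjusted p = 0.00177, adjusted p = 0.147 with an estimated correlation). Trp53inp1 stood at 2.09 ± 0.13 and Pmaip1 at 1.98 ± 0.23. Immediate-early genes had 12 of 28 higher and 5 lower (camera adjusted p = 0.104, 0.0159 with quantile normalization), led by Klf6 (2.27 ± 0.13). Foxq1 had 0.49 ± 0.25 (adjusted p = 0.123). The other lists were not called (camera adjusted p 0.622 or higher). Calls were 4 higher and 14 lower of 37 for extracellular matrix, cell cycle (6 and 10 of 29), interferon (3 and 6 of 27), cholesterol synthesis (4 and 7 of 16), basal (1 and 1 of 15), fibroblast (2 and 1 of 12) and macrophage markers (0 and 2 of 13, 3 at an unadjusted p under 0.05 with limma).

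In NM18 cells the response to TGF-b1 at 40 h was read under control siRNA, which shows the state that FoxQ1 siRNA was set against. E-cadherin (Cdh1) fell by 1.04 ± 0.09 (SE, log2), from 12.26 ± 0.14 to 11.22 ± 0.13 (SD, n = 3 each; limma adjusted p = 1.04e-05), and N-cadherin (Cdh2) rose by 0.77 ± 0.09. Fibronectin (Fn1) rose by 1.89 ± 0.32, from 11.74 ± 0.88 to 13.62 ± 0.08 (adjusted p = 0.000873), and Zeb1 by 0.91 ± 0.12. Lce1f rose by 4.87 ± 0.26 (adjusted p = 1.7e-06), the cathepsin gene Ctsw by 4.72 ± 0.43, Il11 by 3.96 ± 0.50 and thrombospondin 1 (Thbs1) by 3.92 ± 0.29. Il33 fell by 4.78 ± 0.25 (adjusted p = 1.7e-06), Cxcl5 by 4.17 ± 0.28, Ccl20 by 3.61 ± 0.27 and Krt19 by 3.11 ± 0.24. Id1 fell by 1.77 ± 0.15, Id2 by 2.57 ± 0.17 and Id3 by 0.80 ± 0.14. Vim (0.08, adjusted p = 0.331) and Snai1 (0.16, 0.191) were not called. Zeb2 had 0.90 ± 0.24 (adjusted p = 0.0145, 0.0519 with an intensity trend, 0.0653 without array 3 of control siRNA), and Junb 0.75 ± 0.20 (0.0139, 0.0615 without array 1 of control siRNA, 0.0617 without TGF-b1 array 3). TGF-b1 changed 3807 genes, 1642 higher and 2165 lower (178 and 269 by at least 2-fold, 4748 at an unadjusted p under 0.05). With the replicate block, which pairs the arrays, 4785 were called (2106 higher and 2679 lower).

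At 40 h, 19 of 27 mesenchymal and actin cytoskeleton genes rose and 1 fell (the same adjusted over the list alone; median 0.58, camera adjusted p = 7.09e-09, adjusted p = 0.212 with an estimated correlation). Among them were transgelin (Tagln, 2.17 ± 0.13), palladin (Palld, 2.08 ± 0.15) and integrin alpha 5 (Itga5, 1.40 ± 0.09). Early TGF-b/SMAD targets had 17 of 26 higher and 1 lower (the same adjusted over the list alone; median 0.84, camera adjusted p = 1.19e-08, adjusted p = 0.212 with an estimated correlation). Sphk1 rose by 2.14 ± 0.18, the GTPase gene Rhob by 1.90 ± 0.14, Ski by 1.17 ± 0.07, Smad7 by 0.94 ± 0.19 and Klf10 by 0.65 ± 0.09. In the extracellular matrix list 14 of 37 rose and 0 fell (15 and 1 adjusted over the list alone, 17 of either sign at an unadjusted p under 0.05 with limma; camera adjusted p = 0.000128, adjusted p = 0.212 with an estimated correlation). Plod2 rose by 2.25 ± 0.20 and the basement membrane collagen gene Col4a1 by 1.22 ± 0.13. Of the EMT transcription factors 7 of 17 rose and 0 fell (9 and 0 adjusted over the list alone, 9 of either sign at an unadjusted p under 0.05; camera adjusted p = 0.00229, adjusted p = 0.238 with an estimated correlation). Ets1 rose by 0.60 ± 0.12 and Tcf4 by 0.57 ± 0.08. Epithelial genes split, 7 of 42 higher and 12 lower (7 and 13 adjusted over the list alone; camera adjusted p = 0.825): Cdh1 and Krt19 fell, whereas Cldn4 rose by 1.85 ± 0.20 and plakophilin 2 (Pkp2) by 0.83 ± 0.09.

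Of 29 cell cycle genes 25 fell and 0 rose with TGF-b1 (26 and 0 adjusted over the list alone, 26 of either sign at an unadjusted p under 0.05 with limma; median -0.92, camera adjusted p = 3.67e-15, adjusted p = 0.212 with an estimated correlation). The mitotic cyclin gene Ccnb2 fell by 1.42 ± 0.09, Ccna2 fell by 1.14 ± 0.07 and survivin (Birc5) fell by 1.39 ± 0.09. All 15 cholesterol synthesis genes fell (15 adjusted over the list alone; median -1.05, camera adjusted p = 6.56e-08, adjusted p = 0.334 with an estimated correlation). Examples were Lss (-1.10 ± 0.15), Mvd (-1.09 ± 0.16) and the sterol carrier gene Stard4 (-1.05 ± 0.12). In glycolysis 9 of 13 fell and 2 rose (the same adjusted over the list alone; camera adjusted p = 0.00428, adjusted p = 0.461 with an estimated correlation, 0.0783 without cross-hybridising probe sets, 0.0787 above the median level). Pdk1 stood at -1.61 ± 0.22, Ldha at -0.69 ± 0.07 and Hk2 at 1.181 ± 0.138. In oxidative phosphorylation 7 of 23 fell (7 adjusted over the list alone; camera adjusted p = 0.00392, adjusted p = 0.508 with an estimated correlation), including Cyc1 (-0.39 ± 0.07).

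Immediate-early genes were higher as a list, 9 of 26 up and 4 down (11 and 5 adjusted over the list alone; camera adjusted p = 0.0473, adjusted p = 0.508 with an estimated correlation). Jun stood at 1.22 ± 0.11 and the ERK phosphatase gene Dusp6 at -1.61 ± 0.17. The call was lost with median centring (0.0807), above the median level (0.126), without cross-hybridising probe sets (0.0783), without number 2 in every group (0.0516), without arrays 1 (0.0782) and 2 (0.245) of control siRNA alone and without arrays 1 (0.0862) and 3 (0.0962) of control siRNA with TGF-b1. Fibroblast markers had 3 of 12 higher, among them gelsolin (Gsn, 0.74 ± 0.11), and a camera adjusted p of 0.0443 (3 adjusted over the list alone; adjusted p = 0.461 with an estimated correlation). That call was lost with the replicate block (0.0515), quantile normalization (0.0767), without cross-hybridising probe sets (0.0514), without array 3 of control siRNA alone (0.0922) and without array 1 of control siRNA with TGF-b1 (0.0862). The other lists were not called: interferon (3 of 26 higher and 2 lower, camera adjusted p = 0.891; Irgm1 1.07 ± 0.16, Ifit2 -0.64 ± 0.06), p53 (2 of 18 higher and 6 lower, 0.264; Ei24 -0.63 ± 0.06), basal markers (1 higher and 1 lower of 15, 0.434; Jag1 1.16 ± 0.11, Mylk -1.23 ± 0.14) and macrophage markers (1 higher and 1 lower of 13, 0.814; Cd14 -1.09 ± 0.10). Of 22 ribosomal protein genes limma called 0 (2 at an unadjusted p under 0.05; camera adjusted p = 0.261).

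The question of the second set was what FoxQ1 does in TGF-b1-treated cells, and Foxq1 itself was read first in every array. Its log2 level was 7.91, 8.49 and 8.38 with control siRNA alone, 9.08, 9.04 and 9.33 with control siRNA and TGF-b1, and 7.57, 8.09 and 7.97 with FoxQ1 siRNA and TGF-b1. TGF-b1 raised it by 0.89 ± 0.16 (SE; limma adjusted p = 0.00164). FoxQ1 siRNA lowered it to 7.88 ± 0.27 from 9.15 ± 0.16 (SD, n = 3 each), a change of -1.27 ± 0.16 (adjusted p = 0.000291, 2.42-fold). All 3 siRNA arrays lay below all 3 arrays of control siRNA with TGF-b1. With FoxQ1 siRNA, Cdh1 rose by 1.05 ± 0.09, from 11.22 ± 0.13 to 12.27 ± 0.06 (adjusted p = 1.3e-05). Zeb1 fell by 0.53 ± 0.12, from 9.89 ± 0.05 to 9.36 ± 0.15 (adjusted p = 0.00955), and Ets1 by 1.37 ± 0.12. Cdh2 (-0.03, adjusted p = 0.885), Vim (0.01, 0.939), Snai1 (-0.11, 0.443), Zeb2 (-0.23, 0.614), Smad7 (-0.11, 0.768) and Id1 (-0.02, 0.948) were not called. Fn1 had 0.08 ± 0.32 (adjusted p = 0.912), and Id3 -0.38 (adjusted p = 0.0794, 0.0418 with the replicate block). Id2 had 0.78 (adjusted p = 0.00677), not called with the mean of all probe sets (0.0567) or without cross-hybridising probe sets (0.67).

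Skeletal alpha-actin (Acta1) rose the most with FoxQ1 siRNA, by 2.78 ± 0.13 (SE, log2), from 9.16 ± 0.22 to 11.93 ± 0.21 (SD, n = 3 each; limma adjusted p = 2.52e-07). The epoxide hydrolase gene Ephx1 rose by 2.41 ± 0.27, the aldehyde oxidase gene Aox1 by 1.94 ± 0.18, and the brush-border gene villin (Vil1) and the intestinal cadherin gene Cdh17 by 1.82 ± 0.16 and 1.75 ± 0.14. Cathepsin E (Ctse) had 1.85 ± 0.11, with an opposite call in its other probe set. Among the largest falls, the mitotic cyclin gene Ccnb2 fell by 2.33 ± 0.09, from 9.72 ± 0.07 to 7.39 ± 0.18 (adjusted p = 1.72e-07). The proliferation marker Mki67 fell by 2.33 ± 0.13, from 9.97 ± 0.18 to 7.64 ± 0.10, and Cep55 fell by 2.26 ± 0.11. FoxQ1 siRNA changed 2425 genes, 1399 higher and 1026 lower (57 and 140 by at least 2-fold, 3744 at an unadjusted p under 0.05). Without array 1 of control siRNA with TGF-b1 there were 864 higher and 788 lower. With the replicate block 3520 were called (2023 higher and 1497 lower).

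**Figure D2:**
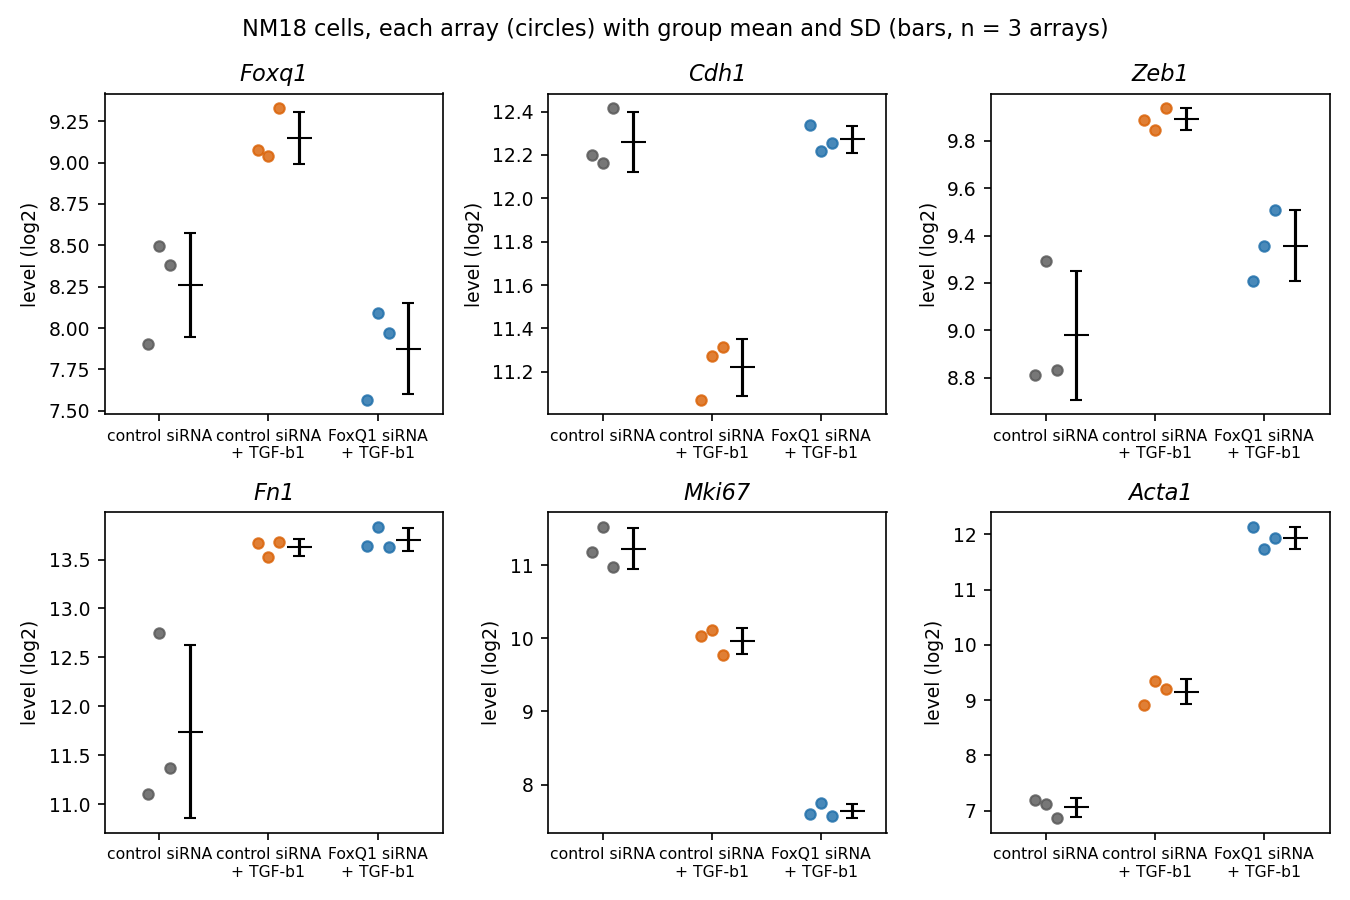
Log2 level (y axis) of Foxq1, Cdh1, Zeb1, Fn1, Mki67 and Acta1 on each NM18 array (circles), for control siRNA, control siRNA with TGF-b1 and FoxQ1 siRNA with TGF-b1 (x axis), with the mean and SD of 3 arrays as bars. Cdh1 goes from 12.26 to 11.22 and back to 12.27, while Fn1 goes from 11.74 to 13.62 and has a further change of 0.08 with FoxQ1 siRNA, and Mki67 falls to 7.64.

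Cell cycle genes fell as a group with FoxQ1 siRNA: 25 of 29 fell and 0 rose (27 and 0 adjusted over the list alone, 27 of either sign at an unadjusted p under 0.05 with limma; median -1.57, camera adjusted p = 2.72e-33, adjusted p = 0.183 with an estimated correlation). Birc5 stood at -2.18 ± 0.09 and Ccna2 at -2.17 ± 0.07. Ribosomal protein genes were lower as a list, 3 of 22 called (3 adjusted over the list alone; median -0.14, camera adjusted p = 0.000483, adjusted p = 0.908 with an estimated correlation, 0.0702 under quantile normalization, 0.0714 without cross-hybridising probe sets). Epithelial genes had 10 of 42 higher and 1 lower (the same adjusted over the list alone; median 0.01, camera adjusted p = 0.142). Higher were Cdh1, Elf3 (0.78 ± 0.09), occludin (Ocln, 0.66 ± 0.09) and the epithelial splicing factor gene Esrp2 (0.42 ± 0.07). EMT transcription factors had 1 of 17 higher, Hmga2 (0.56 ± 0.13), and 4 lower, the siRNA target Foxq1, Zeb1 and Ets1 among them (camera adjusted p = 0.415). Mesenchymal genes had 4 of 27 higher, including Tagln (0.80 ± 0.13), and 3 lower (camera adjusted p = 0.652). Early TGF-b/SMAD targets had 3 of 26 higher, including Ski (0.60 ± 0.07) and the receptor gene Tgfbr1 (0.70 ± 0.17), and 2 lower, including Gadd45b (-1.17 ± 0.15; 0.887).

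Extracellular matrix genes had 1 of 37 higher and 5 lower with FoxQ1 siRNA (1 and 4 adjusted over the list alone; camera adjusted p = 0.142), with the laminin gene Lamc1 at -1.44 ± 0.14 and Plod2 at -1.01 ± 0.20. Immediate-early genes had 4 of 26 higher and 10 lower (4 and 11 adjusted over the list alone; camera adjusted p = 0.142), with Egr2 at 1.62 ± 0.14, Klf4 at -1.11 ± 0.12 and Atf3 at -0.78 ± 0.12. Cholesterol synthesis had 3 of 15 lower and a median of -0.17 (camera adjusted p = 0.142, 0.0296 with the replicate block, 0.0168 without number 2 in every group, 0.0415 and 0.0338 without FoxQ1 siRNA arrays 1 and 3, 0.00472 without array 2 of control siRNA with TGF-b1). Interferon genes had 5 of 26 higher and 1 lower, the chemokine gene Cxcl10 (-1.91 ± 0.27; camera adjusted p = 0.652). Of the p53 targets 3 of 18 were higher: Ephx1, given above among the largest rises, Ei24 (0.85 ± 0.06) and Ccng1 (0.33 ± 0.07; camera adjusted p = 0.675). Macrophage markers had 3 of 13 higher, Cd14 (0.59 ± 0.10), Cd68 (0.50 ± 0.11) and Ptprc (0.35 ± 0.07; 0.875), oxidative phosphorylation 1 higher and 2 lower of 23 (0.652) and glycolysis 1 and 1 of 13 (0.875). Of basal and fibroblast markers limma called 0 of 15 and 0 of 12 (1 and 2 at an unadjusted p under 0.05; camera adjusted p = 0.472 and 0.264). The 18S rRNA control probe set stood at 11.6 ± 0.36 on the 3 arrays numbered 2, 1 per group, and at 13.4 ± 0.12 and 13.4 ± 0.13 on those numbered 1 and 3 (SD, n = 3 each).

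**Figure D3:**
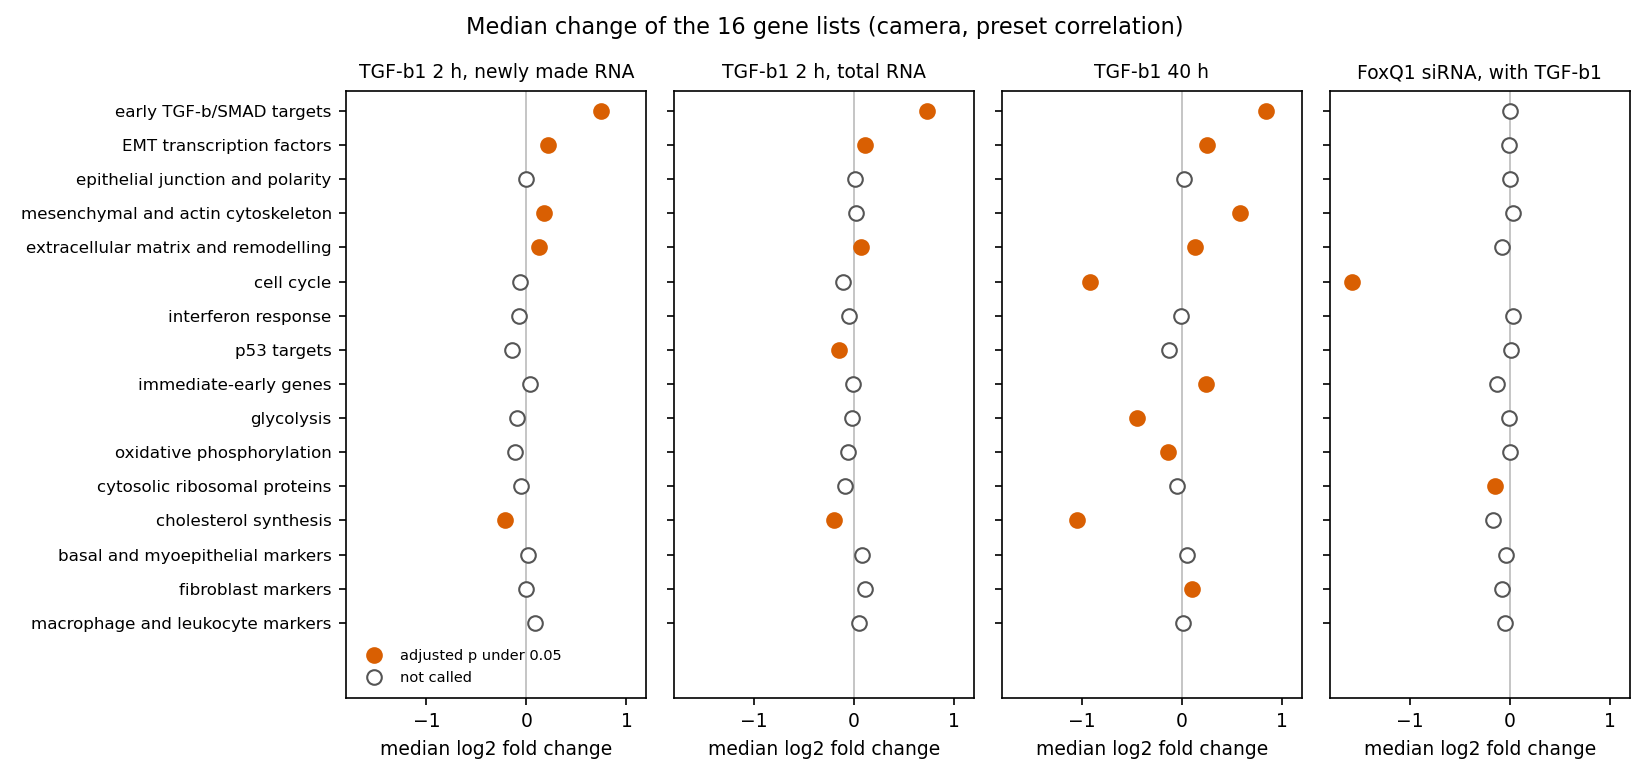
Median log2 fold change (x axis) of the 16 gene lists (y axis) in 4 comparisons: TGF-b1 at 2 h in newly made RNA, in total RNA, TGF-b1 at 40 h and FoxQ1 siRNA. Filled points mark lists with a camera adjusted p under 0.05 at the preset correlation and open points the others. The cell cycle list lies at -0.92 with TGF-b1 at 40 h and at -1.57 with FoxQ1 siRNA, and early TGF-b/SMAD targets at 0.75, 0.73 and 0.84 with TGF-b1.

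How far FoxQ1 siRNA moved the TGF-b1 genes back was counted over the genes called in both comparisons. Cdh1 (-1.04 with TGF-b1, 1.05 with FoxQ1 siRNA) moved back, as did Zeb1 (0.91 and -0.53), Ets1 (0.60 and -1.37), Plod2 (2.25 and -1.01), Cd14 (-1.09 and 0.59) and Lgals2 (-3.26 and 1.73). Of the 3807 TGF-b1 genes, 615 changed in the opposite direction with FoxQ1 siRNA and 680 in the same direction. Among the genes raised by TGF-b1, 207 (12.6%) fell with FoxQ1 siRNA against 136 for independent lists, and among those lowered 408 (18.8%) rose against 244. Same-direction calls numbered 263 and 417, against 185 and 179. Both comparisons contain the 3 arrays of control siRNA with TGF-b1, and 100 simulations of unchanged groups gave a correlation of -0.50 against 0.02 observed and a covariance of -0.0045 against 0.0025. They gave 0 opposite and 0 same-direction calls by limma, which is chance with no effect and does not measure what shared arrays add to real changes. Part of the excess may come from the shared arrays. The count was 1039 with the replicate block and 360 without array 1 of control siRNA with TGF-b1.

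By list, 9 of 13 immediate-early genes called with TGF-b1 moved back and 1 moved further, with Atf3 at 0.61 ± 0.12 (adjusted p = 0.00289) and then -0.78 ± 0.12 (0.00117). Of the EMT transcription factors other than Foxq1, the target of the siRNA, 2 of 6 moved back, Zeb1 and Ets1, and 1 moved further. Of the epithelial genes 5 of 19 moved back, including Cdh1 and Ocln (-0.53 and 0.66), and 2 further. In the p53 list 3 of 8 moved back, including Ei24 (-0.63 and 0.85), and 0 further, and in the extracellular matrix list 3 of 14 and 1 further. Among early TGF-b/SMAD targets 2 of 18 moved back and 3 further, and among mesenchymal genes 1 of 20 and 5 further, Tagln (2.17 and 0.80) among the latter. Cell cycle genes went the other way: 0 of 25 moved back and 24 fell further, for example Ccnb2 (-1.42 and -2.33) and Mki67 (-1.26 and -2.33). Cholesterol genes had 0 of 15 moved back and 3 further.

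Cells with FoxQ1 siRNA and TGF-b1 were also set against untreated control siRNA cells, to see where they stood relative to the starting state. Cdh1 was at 0.01 ± 0.09 (SE, log2; limma adjusted p = 0.943), while Fn1 was 1.96 ± 0.32 higher (adjusted p = 0.000441) and Cdh2 0.74 ± 0.09 higher. Acta1 was 4.88 ± 0.13 higher (adjusted p = 9.24e-10), Lce1f 4.40 ± 0.26 and Tagln 2.96 ± 0.13. Il33 was lower by -4.71 ± 0.25, Ccnb2 by -3.75 ± 0.09 and Mki67 by -3.59 ± 0.13. Foxq1 had -0.39 ± 0.16 (adjusted p = 0.0909, 0.0134 with the replicate block, 0.0449 without FoxQ1 siRNA array 2, 0.0128 without array 1 of control siRNA alone). In total 4695 genes were called, 2392 higher and 2303 lower (261 and 430 by at least 2-fold, 5431 at an unadjusted p under 0.05). With the replicate block 5537 were called (2839 higher and 2698 lower). Lower calls outnumbered higher ones without FoxQ1 siRNA array 3 (2104 higher and 2126 lower) and without array 1 of control siRNA alone (2027 and 2074).

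In that comparison cell cycle genes had 27 of 29 lower and 0 higher (28 and 0 adjusted over the list alone, 28 of either sign at an unadjusted p under 0.05 with limma; median -2.44, camera adjusted p = 2.61e-25, adjusted p = 0.328 with an estimated correlation). All 15 cholesterol genes were lower (15 adjusted over the list alone; median -1.07, camera adjusted p = 1.24e-07, adjusted p = 0.399 with an estimated correlation). Mesenchymal genes had 19 of 27 higher and 2 lower (20 and 2 adjusted over the list alone; camera adjusted p = 3.25e-07, adjusted p = 0.399 with an estimated correlation), with Itga5 at 1.96 ± 0.09. Early TGF-b/SMAD targets had 16 of 26 higher and 2 lower (17 and 2 adjusted over the list alone; camera adjusted p = 3.82e-06, adjusted p = 0.399 with an estimated correlation), with Ski at 1.77 ± 0.07. Ribosomal proteins (10 of 22 lower, 12 adjusted over the list alone) and oxidative phosphorylation (10 of 23 lower, 10 adjusted over the list alone) had camera adjusted p of 0.000262 and 0.00359 (adjusted p = 0.586 with an estimated correlation for both). The extracellular matrix list (10 of 37 higher and 1 lower, the same adjusted over the list alone) had 0.0438 (adjusted p = 0.399 with an estimated correlation). This was lost with the replicate block (0.0571), quantile normalization (0.0729), without FoxQ1 siRNA array 1 (0.0586) and without array 3 of control siRNA alone (0.0690). Glycolysis (2 of 13 higher and 7 lower, 3 and 7 adjusted over the list alone) had 0.0457 (adjusted p = 0.586 with an estimated correlation). It was lost with the replicate block (0.0571), quantile normalization (0.0803), above the median level (0.258), with only the groups compared (0.0581), without cross-hybridising probe sets (0.499), without FoxQ1 siRNA arrays 1 (0.0586) and 2 (0.0940) and without array 3 of control siRNA alone (0.0857). Epithelial genes had 10 of 42 higher, Cldn4 (2.56 ± 0.20) and Jup (1.21 ± 0.11) among them, and 5 lower, Krt19 (-2.71 ± 0.24) among them (camera adjusted p = 0.342). The EMT transcription factor list had 6 of 17 higher and 2 lower (0.232), interferon 8 and 3 of 26 (0.783), p53 4 and 6 of 18 (0.848), immediate-early 5 and 4 of 26 (0.783), basal 1 and 1 of 15 (0.983), macrophage 1 and 1 of 13 (0.830) and fibroblast markers 1 and 0 of 12 (0.520; 2 at an unadjusted p under 0.05).

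The early response of NMuMG cells was set beside the late response of NM18 cells by their calls and log2 changes and not by levels, since the tables were normalized separately and differ in cells and array type. Lce1f and Il11 were higher at both times, and Ccl20, Cxcl5 and Krt19 lower. Over the 12393 genes measured in both, 296 were higher in newly made RNA at 2 h and at 40 h (61.2 for independent lists, two-sided Fisher's exact p = 3.02e-150). In both, 262 were lower (67.4 for independent lists, Fisher's exact p = 1.63e-110), while 30 had opposite calls. Total RNA at 2 h shared 149 higher and 94 lower genes with 40 h and had 14 opposite calls. The changes in newly made RNA and at 40 h correlated at Pearson r = 0.52 across genes. Genes are not independent replicates, which limits the Fisher tests as well. Foxq1 was called higher at both times, but its 2 h call was lost under several alternatives given above. Another probe set stood for Foxq1 at 2 h than at 40 h. The probe set used at 40 h rose by 0.85 in newly made RNA at 2 h (limma adjusted p = 0.0137 over every probe set). Cdh1 was called lower at 40 h (-0.06 at 2 h in newly made RNA), a difference between tables that was not tested.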

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

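The tests of the interferon list, of the p53 list and of a weaker TGF-b1 response were chosen only after the result was seen, and leaving out number 2 in every group was added after seeing the data.

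The TGF-b1 effect differed between newly made and total RNA in 12 genes by the interaction test (newly made minus total, log2). It was -1.88 for Cyp3a13, -1.75 for Vnn1, -1.73 for Akr1c14, -1.73 for Akr1c19, -1.55 for Ccl20, -1.55 for 3110009F21Rik, -1.26 for Egln3, -1.21 for Aldh1a1, -1.14 for Tspan8 and -1.002 for Il33. It was 1.34 for Ctla2a and 1.01 for Epb41l4b. Of 100 drawn splits of the 12 arrays 6 called at least as many genes, the real split with its 12 included, and the highest other called 131. The 5 others as large kept the newly made arrays in their real groups and mixed only total arrays, so they hold the TGF-b1 effect of newly made RNA, a structure of the samples, and are no measure of chance. The 91 splits that mixed the newly made arrays called at most 1 gene, and of 16 drawn splits that parted all 6 pairs 3 were as large, the real one and 2 of those 5. These splits therefore do not decide whether chance can be excluded.

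For the 10 genes with a stronger fall in newly made RNA, the explanations weighed were saturated probe sets and long-lived RNA, where transcripts made before TGF-b1 hide the fall in total RNA. On saturation, the levels of the 10 genes in total control RNA ran from 6.60 to 12.9 (Tspan8, mean of 3 arrays), below the table's highest value of 14.8. That value is not the ceiling of each probe set. The 3 brightest genes, Tspan8, Vnn1 and Aldh1a1, had the smallest changes in total RNA (-0.16, -0.21 and -0.24), so saturation is not excluded for them. With long-lived RNA the genes should be depleted in newly made RNA of control cells, and on the arrays numbered 1 the median newly made minus total level of the 10 genes lay -0.998 from that of the 497 other genes called lower (-1.11 against -0.111, two-sided permutation p = 0.0158, 100000 draws). Noise shared with the interaction acts the other way, by construction, but Ccl20, Cyp3a13 and 3110009F21Rik had positive values (0.656, 0.161 and 0.884), so this explanation may hold for part of the genes only. The permutation treated genes as independent replicates and used 1 array of each kind of control RNA, so it measures no spread between cultures.

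Cell cycle genes were lower with FoxQ1 siRNA by a median of -1.57 (camera adjusted p between 2.85e-36 and 0.183 over 16 alternatives, the highest with an estimated correlation). Against an effect of the arrays numbered 2, whose 18S rRNA probe set was dim, the median was -1.52 without them in every group (adjusted p = 2.62e-29). An interferon response to the siRNA and p53 activation cannot be told apart from an effect of the FoxQ1 knockdown: the interferon list had a median of 0.0319 (95% bootstrap interval -0.121 to 0.172, 26 genes) and the p53 list 0.0169 (-0.140 to 0.176, 18 genes), and medians near 0 over members that went both ways do not decide. The p53 members called by limma were all higher, Ephx1 and Ei24 among them. Off-target effects of the siRNA and an effect of FoxQ1 loss without TGF-b1 were not tested, as the design has 1 siRNA label against FoxQ1 and no FoxQ1 siRNA group without TGF-b1. Of the 10 splits of the 6 arrays 1, the real one, called 2425 genes and the highest other 0, and 10 splits are too few for a share under 0.05.

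FoxQ1 siRNA moved 615 TGF-b1 genes back. Against a weaker TGF-b1 response as a whole, the 38 early TGF-b/SMAD and mesenchymal genes called with TGF-b1 were moved back by a median of -5.39% of their change (95% bootstrap interval -32.0 to 6.15%). The 3 arrays shared by both comparisons could add to the count, and when they were divided so that no array was in both, a mean of 257 genes moved back over 6 divisions (207 to 298), against 148 for independent lists. Opposite calls were above independent lists in all 6 divisions but on average under the bound set beforehand, 0.5 of 615. The division parted the arrays in the log2 changes only, since the spread of a gene was still estimated over all 3 groups. Genes of small spread are easier to call in both comparisons, so independent lists are not a full baseline. Each division also has fewer arrays, so shared arrays and a FoxQ1-dependent part cannot be told apart for the rest. Calls in the same direction exceeded independent lists too (296 to 420 against 122 to 168), so the excess is not particular to movement back, and a role of FoxQ1 in holding these genes in their TGF-b1 state stays a hypothesis.

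For the other counts the 10 splits of 6 arrays are also too few for a share under 0.05. The real split was the 1 of 10 with calls for TGF-b1 in newly made RNA (1116, highest other 0), in total RNA (452 and 0), for newly made against total RNA (8008 and 0), TGF-b1 at 40 h (3807 and 0) and FoxQ1 siRNA with TGF-b1 against untreated cells (4695 and 0), all by limma. Probe sets without a single gene symbol, which only the setting with every probe set on its own included, also carried calls. Of 10092 such NMuMG probe sets limma called 304 for TGF-b1 in newly made and 65 in total RNA, and of 2246 NM18 probe sets 430 for TGF-b1 at 40 h and 270 with FoxQ1 siRNA.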

How the results depend on the processing

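The blocks within each kind of RNA and the settings without number 1 or number 2 in every group were chosen after seeing the data. The count of called genes stayed within 1.5 times of the reported one in each comparison under median centring, with genes above the median level only, with an intensity trend, with the mean of all probe sets and without cross-hybridising probe sets, and in the NM18 comparisons without number 2 in every group. With only the arrays of the groups compared, TGF-b1 called 680 genes in newly made RNA in place of 1116 and 586 in total RNA in place of 452. That setting keeps the log2 changes and alters only the estimate of the spread and its degrees of freedom. The gap between 1116 and 452 thus depends on the shared estimate. Newly made arrays were less alike within groups (lowest r 0.984 in control and 0.989 with TGF-b1) than total arrays (0.992 and 0.994). The shared spread may therefore be too small for newly made and too large for total RNA. Quantile normalization gave 19 interaction genes in place of 12, and the cause was not tested. With every probe set on its own more features are tested, and 1913 probe sets were called for TGF-b1 in newly made RNA, 19926 for newly made against total RNA, 6281 for TGF-b1 at 40 h, 3854 with FoxQ1 siRNA and 8047 for FoxQ1 siRNA with TGF-b1 against untreated cells. With the replicate block, a paired fit, the counts were 1602, 701 and 39 for TGF-b1 in newly made RNA, in total RNA and their difference, 4785, 3520 and 5537 in the NM18 comparisons, and 1039 for genes moved back. A block within each kind of RNA gave 2320, 1025 and 86. In newly made against total RNA, where numbers pair the arrays only in part, the block gave 8571 genes in place of 8008. There 142 called genes had an opposite call with the mean of all probe sets and 132 without cross-hybridising probe sets. No scaling moved the share of higher calls by over 10 percentage points, but some moves came near that. In newly made against total RNA the share was 39.1%, 48.7% with median centring and 32.1% with quantile normalization. For TGF-b1 in newly made RNA it was 54.6%, and 63.6% with median centring.

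Leaving out each array in turn gave 758 to 1288 genes for TGF-b1 in newly made RNA, 308 to 358 in total RNA, 7424 to 8048 for newly made against total RNA, 3103 to 3741 for TGF-b1 at 40 h, 1652 to 2143 with FoxQ1 siRNA and 4078 to 4572 for FoxQ1 siRNA with TGF-b1 against untreated cells. Genes called at 2 h and 40 h numbered 419 to 617, and genes moved back 360 to 603, with 360 without array 1 of control siRNA with TGF-b1. The interaction gave 4 to 20: 20 without array 1 of newly made control RNA, 6 and 5 without arrays 2 and 3, 5 without total control array 1 or 2, 7 without newly made TGF-b1 array 3 and 4 without total TGF-b1 array 1 or 2. Without number 1 in every group it gave 25, of fewer arrays, and the cause was not tested.

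Of the values of named genes under alternatives, 9747 kept direction and side of the threshold, 227 lost and 173 gained a call, and 6 turned. In newly made against total RNA, Fn1 had 0.56 (limma adjusted p = 0.0417) with the mean of all probe sets. Without cross-hybridising probe sets Lmna had 0.23, Pfkl 0.67, Cox5b 0.32 and Rpl35 0.32 there, and Srf had 0.11 with FoxQ1 siRNA, since another probe set then stands for the gene. Of the list tests 1804 kept direction and side of the threshold, 94 lost and 21 gained a call, and 0 turned. Of the 94 lost calls 36 came with an estimated correlation. The replicate block gave 35 more gene calls and lost 0, and among list tests gained 2 and lost 3 calls. The list calls it changed, and the gene calls it changed among genes given as not called, stand beside those results, and it changed no other list call. Signal over background limits what can be read for dim genes: 10% of the values lay below 3.98 in the NMuMG and below 5.58 in the NM18 table (log2), close to the lowest values of 2.34 and 4.57, so changes of such genes may be understated, and with genes above the median level only, TGF-b1 called 968 genes in newly made RNA.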

Other observations

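The tests of early against late calls were chosen only after the result was seen, and so was the choice of Pdgfrb. In NMuMG cells the growth factor receptor gene Pdgfrb, a fibroblast marker, differed between replicate numbers as well as with TGF-b1. Its log2 level in newly made control RNA was 6.70, 8.76 and 8.09 on arrays 1, 2 and 3, and 8.13, 9.88 and 9.39 with TGF-b1. In total RNA it was 5.71, 7.32 and 7.28 without and 6.75, 8.26 and 7.90 with TGF-b1. The change was 1.28 ± 0.55 in newly made RNA (limma adjusted p = 0.245), and with the replicate block the adjusted p was 7.63e-07, the lowest of its alternatives but for 3.28e-08 with a block within each kind of RNA, and the highest was 0.545 without TGF-b1 array 2. In all 3 pairs of each kind of RNA it was higher with TGF-b1. In NM18 cells it stood between 5.98 and 6.30 on each array.

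Several genes with a stronger fall in newly made than in total RNA at 2 h were also lower at 40 h in NM18 cells: Il33 by -4.78 ± 0.25 (SE, log2), Ccl20 by -3.61 ± 0.27, Tspan8 by -3.07 ± 0.22, Aldh1a1 by -2.73 ± 0.53, Vnn1 by -2.65 ± 0.28, Akr1c14 by -1.87 ± 0.15, Egln3 by -1.83 ± 0.19 and Cyp3a13 by -0.96 ± 0.12. A hypothesis was that genes called lower in newly made but not in total RNA at 2 h are lower at 40 h. For most such genes a difference between the kinds of RNA is not shown, since the test of that difference called 12 genes in all. Of 281 such genes 65.8% were lower at 40 h, against 16.2% of genes called in neither (two-sided Fisher's exact p = 1.58e-74) and 73.3% of 105 called lower in both. Of 266 genes called higher in newly made but not in total RNA, 58.6% were higher at 40 h, against 11.5% (two-sided Fisher's exact p = 4.75e-73) and 71.4% of 196 called in both. Opposite calls at 40 h numbered 7 and 11. Genes are not independent replicates for the Fisher tests, and genes called in neither were not filtered by level. Dim genes among them are harder to call at either time, so these p do not measure persistence alone. These shares are in line with early transcription changes that last, but cells, array types and detection limits differ between the tables, and the difference from genes called in both kinds of RNA was not tested. Across genes, which are not independent replicates, the difference of the TGF-b1 effect (arrays 2 and 3) and the newly made minus total level of control cells (array 1) had a Spearman correlation of 0.40 over 507 genes called lower and -0.17 over 609 called higher in newly made RNA.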
